A study of Mus musculus with 7 samples.

How the data were processed

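Retinas of mice infused with angiotensin II (Ang II, the pressor peptide of the renin-angiotensin system) or with saline were sampled on day 28 and sequenced as poly-A selected RNA, 4 Ang II libraries and 3 saline libraries. Per the labels' protocols, cDNA was primed with random hexamers and adaptors with a hairpin loop were ligated, without a step that marks the strand. Reads from a gene and from an antisense or overlapping partner are therefore not separable in these values. The deposited table holds whole-number counts per gene, one column per library, and the authors did not normalize these counts. Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the genome build was mm10. The annotation release, the counting rules for reads that match several genes and the strand setting were not given in the sources used here. Genes with near-identical copies, such as Gapdh, ribosomal protein genes, globins and mitochondrially encoded genes, are uncertain for that reason. Of the 54532 gene IDs in the table, 54409 were found in GENCODE M21 on the same build, and 98.3% of those had the same start and end.

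Library columns were matched to samples by the sample descriptions, and 0 columns of per-library values were left unmatched. Groups followed the sample titles. The series text gives the mice as ApoE-/-, whereas the sample labels give the genotype as WT, so Apoe was reported in every library before anything else. Replicate numbers 1 to 3 occur in both groups, but no label says that they pair animals, and no label says from how many animals each library came. The p-values of single genes and of shares of counts measure the spread between these libraries.

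The main test was the quasi-likelihood test of edgeR 4.0.16 with robust dispersion in R 4.3.3, two-sided, on the deposited counts of all 7 libraries, with the group as the sole term. Genes were kept by filterByExpr with the group, libraries were scaled by TMM, and p-values were adjusted by the Benjamini-Hochberg method, with adjusted p under 0.05 as the threshold. Fold changes are Ang II over saline on the log2 scale. The standard error (SE) of a gene was back-calculated from the test, as the absolute log2 fold change over the square root of its F statistic. Levels are CPM, the read count relative to the TMM-scaled library size as edgeR computes it, and log2 CPM used a prior count of 2. The 39 gene lists (cell type markers, neighbouring tissues and pathways) were fixed before the data were examined, and 38 of them, leaving out sex-linked genes, were tested with camera of limma 3.58.1 at a preset correlation of 0.01. At the preset correlation, camera sets the genes of a list against the other genes and takes them as nearly independent. Its p-values therefore rest largely on the spread between genes rather than between libraries. An estimated correlation and fry were run beside it. Where a symbol has more than 1 gene ID, the ID with most counts was used, which concerned 3 listed symbols. Shares of counts in 5 tissue or mitochondrial lists were compared with exact two-sided permutation tests over the 35 arrangements of the libraries. Intervals of single shares are Wilson 95% intervals, and a count of 0 was taken to allow up to 3 counts. Both cover counting error alone, since reads without molecular identifiers are not independent molecules.

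Genes named in the text followed a rule set before the data were examined. It takes genes past the threshold with a mean of at least 1 CPM, a gene symbol that is not a model name, and no overlap between the groups. Where fewer than 5 passed in a direction, that direction was filled to 5 with the genes of smallest p under the other conditions. It adds the members of smallest p of each list, and Apoe, Agt, Agtr1a, Agtr1b, Agtr2, Ace, Gfap and Vegfa. Some genes that the rule takes are not reported here. Any other gene in the text was chosen after its values were seen, and these are further members of the lists and the genes called by another tool or without a library.

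The steps were tested on simulated data. For Ang II against saline, counts were drawn for the real genes from the means and library sizes of the samples. In them 200 genes were changed, and 16736 genes entered the step. The changed genes all had a mean of at least 1 CPM, so recovery at lower levels was not tested. Of the 100 genes changed by a log2 fold of 1, 77% were called, and of the 100 changed by a log2 fold of 2, 97% were called, each in the right direction. Of 184 calls, 10 were false (5.43%). A simulated shift of 0.3 on the log2 scale in the synaptic list was called among 38 lists, and 0 other lists were called. Each simulated gene was drawn independently of the others. In the real data the estimated correlation was 0.42 for pigment epithelium, 0.93 for skeletal muscle and -0.01 for immediate early genes. The simulation therefore cannot say how often lists of genes that move together are falsely called. Whether as large a share of changed genes would be recovered in the real libraries was not tested.

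The alternatives set before the data were examined were other scalings (DESeq2 size factors, upper quartile, library size), other filters on low counts, DESeq2 1.42.0, limma-voom with sample quality weights, edgeR without robust dispersion, a fold threshold, an adjusted p under 0.1, protein-coding genes alone, removal of tissue genes, a lens score as a covariate, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were a pigment epithelium score as a covariate, Ang II replicates 2 and 3 left out together, and the newer dispersion method of edgeR (legacy = FALSE). That score, a mean log2 CPM, was 4.15 ± 0.343 (SD, n = 4) in Ang II and 2.86 ± 0.890 (SD, n = 3) in saline. As a covariate it takes up part of the group difference. A call that ends with it is therefore not shown to come from pigment epithelium RNA. The list tests were not rerun with DESeq2, with the fold threshold or with the newer dispersion method. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.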

Results

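The series asked how 28 days of Ang II infusion alter the transcriptome of the mouse retina, the neural tissue at the back of the eye. Gene counts of 4 retina libraries from Ang II-infused mice were compared with those of 3 from saline-infused mice. Total counts per library were 17563493, 16376913, 15374638 and 16286251 for Ang II replicates 1 to 4, and 16679829, 14655431 and 16365474 for saline replicates 1 to 3. The mean depth was 16400324 ± 897878 counts (SD, n = 4) in Ang II and 15900245 ± 1089438 counts (SD, n = 3) in saline. Between 21260 genes (saline replicate 2) and 24846 genes (Ang II replicate 3) had at least 1 count.

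Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, mm10), which encodes apolipoprotein E and is the gene the series text gives as deleted, had counts in every library. Its counts were 291, 253, 406 and 373 in Ang II replicates 1 to 4 and 304, 150 and 273 in saline replicates 1 to 3. The level was 20.04 ± 4.87 CPM (SD, n = 4) in Ang II and 15.3 ± 4.32 CPM (SD, n = 3) in saline, a log2 fold change of 0.38 ± 0.22 (SE) with an edgeR adjusted p of 0.982. Knockout alleles can leave part of a transcript in place, so these counts do not decide between the genotypes that the series text and the sample labels give. The libraries resembled each other closely, with Spearman correlations of log2 CPM between 0.976 and 0.990 across genes, and no pair agreed within sampling noise (chi-square per degree of freedom 10.01 to 25.1). The first principal component held 33.3% of the variance and set saline replicate 2 apart from the other 6 libraries, while the treatment groups were not separated along it.

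As lists, markers of the pigment epithelium, the pigmented layer behind the photoreceptors, were higher in Ang II, and markers of rods, cones and bipolar cells were slightly lower, by camera with a preset correlation. With an estimated correlation 0 lists were called (smallest adjusted p = 0.437), and edgeR called 0 single genes where DESeq2 called 35 and limma-voom 114. Pigment epithelium markers lay higher by a median log2 fold change of 1.40, among them the retinoid-cycle genes Rpe65 (152.6 ± 40.0 CPM in 4 Ang II against 45.9 ± 40.1 CPM in 3 saline libraries, mean ± SD) and Rdh5 (83.1 ± 26.1 against 22.7 ± 21.3 CPM). Rod genes lay lower by a median of -0.20, and all 15 of them were on that side. The gliosis genes Gfap, Edn2 and Serpina3n were far higher in Ang II replicate 3 than in the other 6 libraries. Markers of vascular cells, microglia and cytokine or interferon pathways were not called as lists.

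With edgeR, 0 of 17078 tested genes were called, 0 higher and 0 lower, and the smallest adjusted p was 0.226. An unadjusted p under 0.05 was found for 789 genes, 496 higher and 293 lower in Ang II, where 853.9 would be expected by chance. The groups did not overlap in 1010 genes (5.91%), and chance gives 5.71%. DESeq2 called 35 genes (31 higher, 4 lower) and limma-voom with quality weights called 114 (98 higher, 16 lower). Those weights were 3.33, 0.430 and 0.632 for saline replicates 1 to 3, and 0.597 to 2.13 in Ang II. The saline side of the limma-voom count thus rests mostly on 1 library. Without saline replicate 3, edgeR called 117 genes, 103 higher and 14 lower. Of the genes named here, 15 were among them, 12 higher (Rdh10, Tyr, Tbc1d1, Slc22a8, Slc39a12, Cat, Rbm47, Csf1r, Rdh5, Plin2, Rpe65 and Apold1) and 3 lower (Hk2, Slco4a1 and Ckmt1).

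The 5 named genes of smallest p that lay higher did not pass. They were Slc39a12, a zinc transporter gene (ENSMUSG00000036949, chromosome 2, 14388316 to 14494977), at 7.75 ± 1.85 CPM (SD, n = 4) against 2.40 ± 0.970 CPM (SD, n = 3), log2 fold change 1.68 ± 0.29 (SE), edgeR adjusted p = 0.226; Slc22a8, an organic anion transporter gene (ENSMUSG00000063796, chromosome 19, 8591254 to 8611834), at 10.9 ± 1.39 against 4.52 ± 1.45 CPM, log2 fold change 1.27 ± 0.22, adjusted p = 0.226; and Tbc1d1, which encodes a Rab GTPase-activating protein (ENSMUSG00000029174, chromosome 5, 64156305 to 64351486), at 45.2 ± 5.52 against 25.2 ± 6.10 CPM, log2 fold change 0.84 ± 0.15, adjusted p = 0.295. Apold1, an early response gene of endothelial cells, and Rbm47, which encodes an RNA-binding protein, had log2 fold changes of 1.07 ± 0.21 and 1.65 ± 0.32, both with adjusted p = 0.312. Each of these 5 was higher in all 4 Ang II libraries than in any saline library, which the naming rule required, so this adds no evidence. DESeq2, run on the same counts, called all 5. On the lower side, the mitochondrial creatine kinase gene Ckmt1 had a log2 fold change of -0.49 ± 0.10 (87.6 ± 10.7 against 122.7 ± 9.06 CPM, adjusted p = 0.490). It was followed by the processed pseudogene Vcp-rs (-0.46 ± 0.10, adjusted p = 0.540), the growth factor binding protein gene Igfbp3 (-0.84 ± 0.20, adjusted p = 0.587), the transporter gene Slco4a1 (-0.46 ± 0.12, adjusted p = 0.835) and the phosphatase gene Dusp5 (-0.49 ± 0.14, adjusted p = 0.875). Vcp-rs is a near copy of a coding gene, so its reads are uncertain.

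Pigment epithelium and melanocyte markers were higher as a list, with 13 of 14 members above 0, a median log2 fold change of 1.40 and a camera adjusted p of 3.51e-13. With an estimated correlation the adjusted p = 0.437, and fry gave an adjusted p of 0.327. With edgeR, 0 members passed over all genes, and 2 passed when adjusted over the list alone. DESeq2 called 1 member over all genes, Tyr (adjusted p = 4.92e-05). These were Tyr, the tyrosinase gene of melanin synthesis (log2 fold change 1.90 ± 0.34, adjusted p over the list 0.00179), and Mitf, the transcription factor gene of pigment cells (0.51 ± 0.14, 0.0201). Rdh5 and Rpe65, which act in the visual cycle, had log2 fold changes of 1.87 ± 0.69 and 1.73 ± 0.64 (adjusted p over the list 0.117 for both). The list took 0.147% ± 0.0365 (SD, n = 4) of the counts in Ang II and 0.0468% ± 0.0452 (SD, n = 3) in saline, higher in 4 of 4 Ang II libraries than in any saline library, with an exact permutation p of 0.0286, the smallest that 35 arrangements allow, and 0.143 after adjustment over 5 shares. Saline replicate 3 lay between the groups, with 0.0990% (Wilson 95% interval 0.0974 to 0.1005), while saline replicates 1 and 2 had 0.0191% and 0.0224%. Without saline replicate 3 the list median was 2.12.

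**Figure D1:**
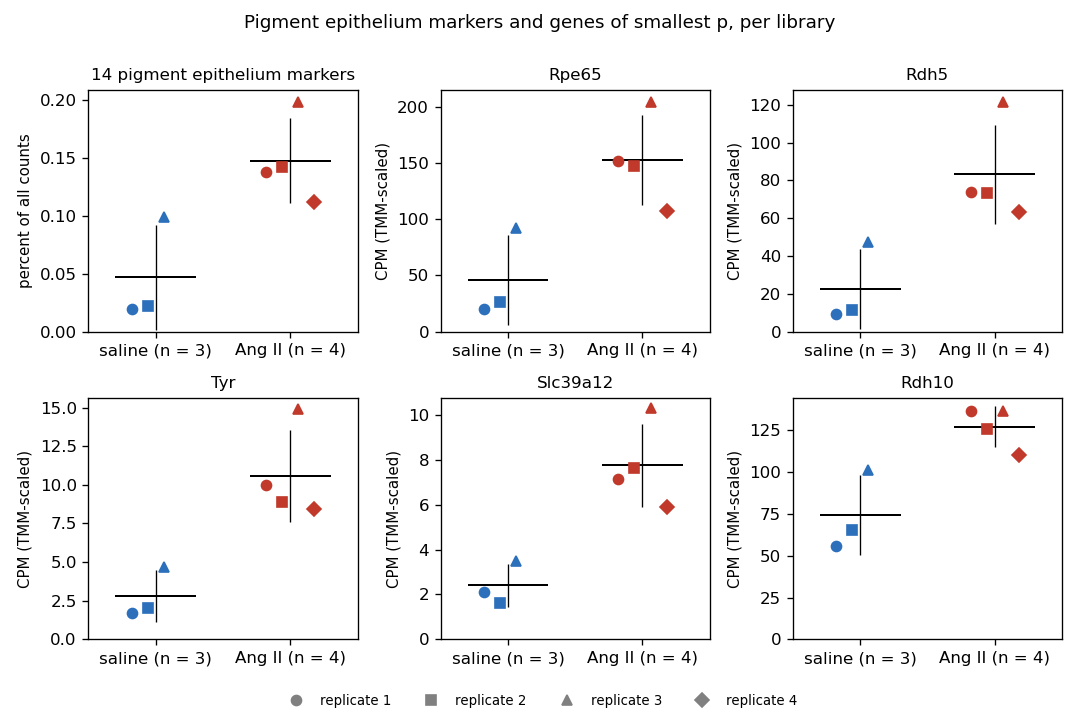
Share of counts (percent) in the 14 pigment epithelium markers and TMM-scaled CPM of 5 genes, by group; each symbol is a library, its shape gives the replicate number, horizontal lines are means and vertical lines ± SD (cut at 0). The shares of the 4 Ang II libraries lie between 0.111% and 0.198%, and saline replicate 3 lies at 0.0990%, nearer to them than the other saline libraries.

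Photoreceptor and bipolar cell genes were lower as lists. All 15 rod markers had a log2 fold change below 0, with a median of -0.20 and a camera adjusted p of 9.69e-07 (adjusted p = 0.437 with an estimated correlation). Pde6g, the inhibitory subunit gene of the rod phosphodiesterase, was at 1434.7 ± 120.8 CPM (SD, n = 4) in Ang II and 1757.5 ± 148.1 CPM (SD, n = 3) in saline, a log2 fold change of -0.29 ± 0.09. The rod transcription factor gene Nrl (-0.21 ± 0.09), the disc protein gene Rom1 (-0.21 ± 0.09) and the transducin subunit gene Gngt1 (-0.24 ± 0.10) had edgeR adjusted p of 0.982, like Pde6g. The 10 cone markers all lay below 0 (median -0.17, camera adjusted p = 0.00273, adjusted p = 0.437 with an estimated correlation), among them the cone opsin gene Opn1mw (-0.32 ± 0.16), Gnat2 (-0.25 ± 0.13), Pde6c (-0.22 ± 0.11) and Pde6h (-0.39 ± 0.20). The cone call ended without saline replicate 1 (0.0543) and without saline replicate 2 (0.0557), and with the pigment epithelium score as a covariate (0.831). The 13 bipolar markers all lay below 0 (median -0.11, camera adjusted p = 0.00377, adjusted p = 0.497 with an estimated correlation), including Cabp5 (-0.18 ± 0.08), Isl1 (-0.17 ± 0.09) and Scgn (-0.19 ± 0.11). The bipolar call ended with that covariate (0.816) and without Ang II replicates 2 and 3 (0.0520), while the rod call was kept with it (1.31e-05, median -0.25). In these 3 lists 0 members passed with edgeR, over all genes or adjusted over the list alone, and the share of pigment epithelium counts moved the other way.

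Other retinal cell types showed no call as lists. Amacrine markers had a median of -0.03 (camera adjusted p = 0.402), with Slc17a8 at -0.21 ± 0.14 and Gad2 at 0.12 ± 0.09. Ganglion cell markers had a median of -0.02 (0.402), with Isl2 at -0.30 ± 0.16 and Pou4f3 at -0.30 ± 0.24. Horizontal cell markers had a median of 0.12 (0.783), with Calb1 at -0.15 ± 0.16 and Onecut1 at 0.23 ± 0.32. Müller glia markers had a median of 0.03 (0.503), and 1 of 12 passed when adjusted over the list alone. That gene was Rdh10, a retinol dehydrogenase gene also used by the pigment epithelium (127.3 ± 12.5 against 74.2 ± 23.9 CPM, log2 fold change 0.78 ± 0.19, adjusted p over the list 0.0314), which DESeq2 called over all genes (adjusted p = 0.00336), and Clu followed with 0.31 ± 0.12. Synaptic genes had a median of -0.04 (0.0907), with the glutamate transporter gene Slc17a7 at -0.25 ± 0.08 and Syp at -0.20 ± 0.10.

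Reactive gliosis genes, which glia turn on after injury, were higher as a list, with 13 of 15 members above 0, a median of 0.37 and a camera adjusted p of 0.00658 (adjusted p = 0.635 with an estimated correlation). Gfap, the intermediate filament gene of reactive glia, was at 79.8 CPM in Ang II replicate 3 and between 6.84 and 9.60 CPM in the other 6 libraries, a group log2 fold change of 1.45 ± 1.15. In the same library the endothelin gene Edn2 was at 30.5 CPM (at most 3.65 elsewhere) and the protease inhibitor gene Serpina3n at 53.4 CPM (at most 8.80 elsewhere), with log2 fold changes of 2.34 ± 1.52 and 1.62 ± 1.14. Without Ang II replicate 3 the list's adjusted p was 0.7001, and the log2 fold changes were -0.29 for Gfap, 0.26 for Edn2 and 0.12 for Serpina3n. The call also ended without saline replicate 1 (0.0543), without saline replicate 3 (0.154), without Ang II replicates 2 and 3 (0.714, direction turned) and with the pigment epithelium covariate (0.405). Osmr, a cytokine receptor gene that was higher in all 4 Ang II libraries than in any saline library (0.87 ± 0.27), and Cd44, an adhesion receptor gene (0.56 ± 0.23), had edgeR adjusted p of 0.982, and 0 members passed when adjusted over the list alone.

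Complement genes were higher as a list (7 of 10 above 0, median 0.65, camera adjusted p = 0.0235, adjusted p = 0.497 with an estimated correlation). Among its members, the protease gene Cfi had a log2 fold change of 0.99 ± 0.43, the protease gene C1s1 of 0.72 ± 0.39 and Cd59a, which encodes an inhibitor of the membrane attack complex, of -0.24 ± 0.12, and with edgeR 0 members passed when adjusted over the list alone. The list's call ended without Ang II replicate 3 (0.178), without saline replicate 1 (0.0899), without saline replicate 3 (0.109), without Ang II replicates 2 and 3 (0.714), with library size as the scaling (0.0544) and with the pigment epithelium covariate (0.405). Microglia and macrophage markers had a median of 0.06 (camera adjusted p = 0.705). Of these, 1 of 13 passed when adjusted over the list alone, the growth factor receptor gene Csf1r (24.5 ± 1.69 against 16.1 ± 3.55 CPM, log2 fold change 0.61 ± 0.15, adjusted p over the list 0.0132), while C1qc was at 0.42 ± 0.23. Lymphocyte and neutrophil markers (median 0.17, 0.299) had 3 tested members, with S100a9 at 1.75 ± 0.84 and Ighm at -0.17 ± 0.46. Cytokine, chemokine and adhesion genes (median 0.06, 0.983) had 4, with Il18 at 0.22 ± 0.22 and Vcam1 at -0.16 ± 0.16. Interferon response genes (median 0.11, 0.178) included Gbp3 at 0.84 ± 0.25 and Bst2 at 0.67 ± 0.32, and antigen presentation genes (median 0.06, 0.543) included B2m at 0.18 ± 0.12 and Psme2 at 0.25 ± 0.20.

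**Figure D2:**
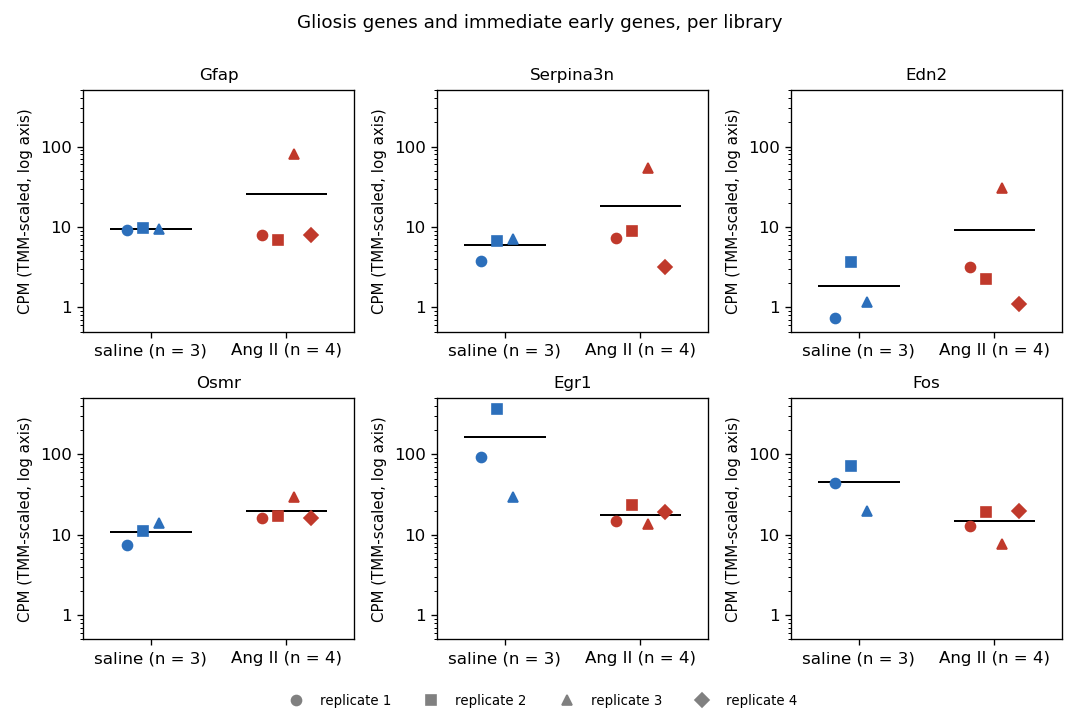
TMM-scaled CPM (log axis) of 4 gliosis genes and 2 immediate early genes by group; each symbol is a library, its shape gives the replicate number, and horizontal lines are group means. Gfap reached 79.8 CPM in Ang II replicate 3, and Egr1 reached 366.8 CPM in saline replicate 2.

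Renin-angiotensin system genes, the pathway that makes and senses Ang II, were not called as a list (median -0.01, camera adjusted p = 0.783). Agt, the precursor of Ang II, was at 8.79 ± 0.630 CPM (SD, n = 4) in Ang II and 8.85 ± 1.90 CPM (SD, n = 3) in saline, a log2 fold change of -0.01 ± 0.18. Ace was at -0.05 ± 0.18, Mme at 0.67 ± 0.33 and Nln at 0.20 ± 0.18. The receptor genes were too low to be tested. Agtr1a had 2 to 6 counts per library in Ang II and 6 to 27 in saline, where the 27 came from saline replicate 2. Agtr2 had 5 to 12 and 6 to 10 counts, and Agtr1b had 1 count in Ang II replicate 4 and 0 in the other 6 libraries, which allows up to 0.205 CPM in the shallowest of them. NADPH oxidase genes, a source of superoxide, had a median of 0.29 (0.178), with Ncf1 at 0.36 ± 0.39. Antioxidant genes had a median of 0.02 (0.0799), with the metallothionein gene Mt2 at 1.61 ± 0.45 and the catalase gene Cat at 0.48 ± 0.17.

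Vascular and matrix lists were not called. Endothelial markers had a median of -0.02 (camera adjusted p = 0.874), with Slco1a4 at 0.43 ± 0.15 and Ocln at -0.41 ± 0.23. Pericyte and smooth muscle markers had a median of 0.08 (0.783), with Myh11 at -0.42 ± 0.21 and Acta2 at 0.37 ± 0.23. Matrix and TGF-beta genes had a median of 0.08 (0.249), with Tgfb1 at 0.77 ± 0.34 and Postn at 0.57 ± 0.31. Hypoxia and angiogenesis genes had a median of -0.05 (0.874). Among them Vegfa, the main angiogenic factor gene, was at 131.9 ± 17.7 CPM (SD, n = 4) against 120.9 ± 16.4 CPM (SD, n = 3), a log2 fold change of 0.13 ± 0.12, the lipid droplet gene Plin2 was at 0.92 ± 0.28 and Hk2 at -0.46 ± 0.32. Without saline replicate 3 these were 1.37 (edgeR adjusted p = 0.0188) and -0.76 (0.000760), and Hk2 was -0.18 without saline replicate 1.

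Glycolysis genes were lower as a list, with 15 of 16 members below 0, a median of -0.13 and a camera adjusted p of 0.00273 (adjusted p = 0.497 with an estimated correlation). Ldha (-0.23 ± 0.10), Eno2 (-0.18 ± 0.09), Eno1 (-0.20 ± 0.10) and Pkm (-0.15 ± 0.09) had the smallest p, and the call ended without saline replicate 1 (0.0543) and with the pigment epithelium covariate (0.816). Cytosolic ribosomal protein genes were lower too (18 of 20 below 0, median -0.09, camera adjusted p = 0.00186, adjusted p = 0.437 with an estimated correlation), and this call ended without saline replicate 3 (0.163). Rpl27 (-0.20 ± 0.08), Rpl37 (-0.26 ± 0.11), Rps27a (-0.83 ± 0.32) and Rplp2 (-0.17 ± 0.11) led them, all genes with near copies. Immediate early genes, which respond within minutes to activity or handling, were lower as a list (10 of 14 below 0, median -0.11, camera adjusted p = 0.0344, adjusted p = 0.437 with an estimated correlation). Egr1 was at 17.8 ± 4.57 CPM (SD, n = 4) in Ang II, and at 93.5, 366.8 and 29.3 CPM in saline replicates 1 to 3, a log2 fold change of -3.19 ± 0.90. Fos (-1.61 ± 0.54) and Ier2 (-0.96 ± 0.28, DESeq2 adjusted p = 0.0250) were likewise below every saline library, whereas Fosb lay the other way (0.45 ± 0.23). Without saline replicate 2 Egr1 was at -1.79, Fos at -1.11 and Ier2 at -0.49. With the pigment epithelium covariate, which itself differs between the groups, they were at -0.37, -0.23 and -0.20. The call ended without Ang II replicate 1 (0.0725), Ang II replicate 3 (0.227) or saline replicate 1 (0.129), without Ang II replicates 2 and 3 (0.380), and with the lens (0.0578) or pigment epithelium (0.816) score as a covariate. In glycolysis, ribosomal and immediate early genes 0 members passed with edgeR when adjusted over the list alone.

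The remaining pathway lists were not called. Nuclear oxidative phosphorylation genes had a median of -0.05 (camera adjusted p = 0.0751), with Atp5b at -0.17 ± 0.08 and Uqcrc1 at -0.18 ± 0.08. Mitochondrially encoded genes had a median of 0.00 (0.783), with mt-Atp6 at 0.54 ± 0.25 and mt-Co3 at -0.31 ± 0.18. Cholesterol synthesis genes had a median of 0.07 (0.0751), with Stard4 at 0.26 ± 0.11, and lipid transport genes had a median of 0.02 (0.874), with Lcat at -0.99 ± 0.40 and Abca4 at -0.22 ± 0.10. Stress lists included the unfolded protein response (median -0.01, 0.983, Chac1 at 0.46 ± 0.25 and Dnajb9 at 0.19 ± 0.12) and heat shock genes (median -0.03, 0.402, Hspe1 at -0.23 ± 0.11 and Hsp90aa1 at -0.17 ± 0.10). Circadian clock genes had a median of -0.06 (0.0799), with Nr1d1 at -0.23 ± 0.10 and Per2 at -0.38 ± 0.18. Cell death genes had a median of 0.33 (0.0907), with Tnfrsf1a at 0.48 ± 0.21. In 9 uncalled lists the signs of the median, the mean and the camera direction were not all alike.

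**Figure D3:**
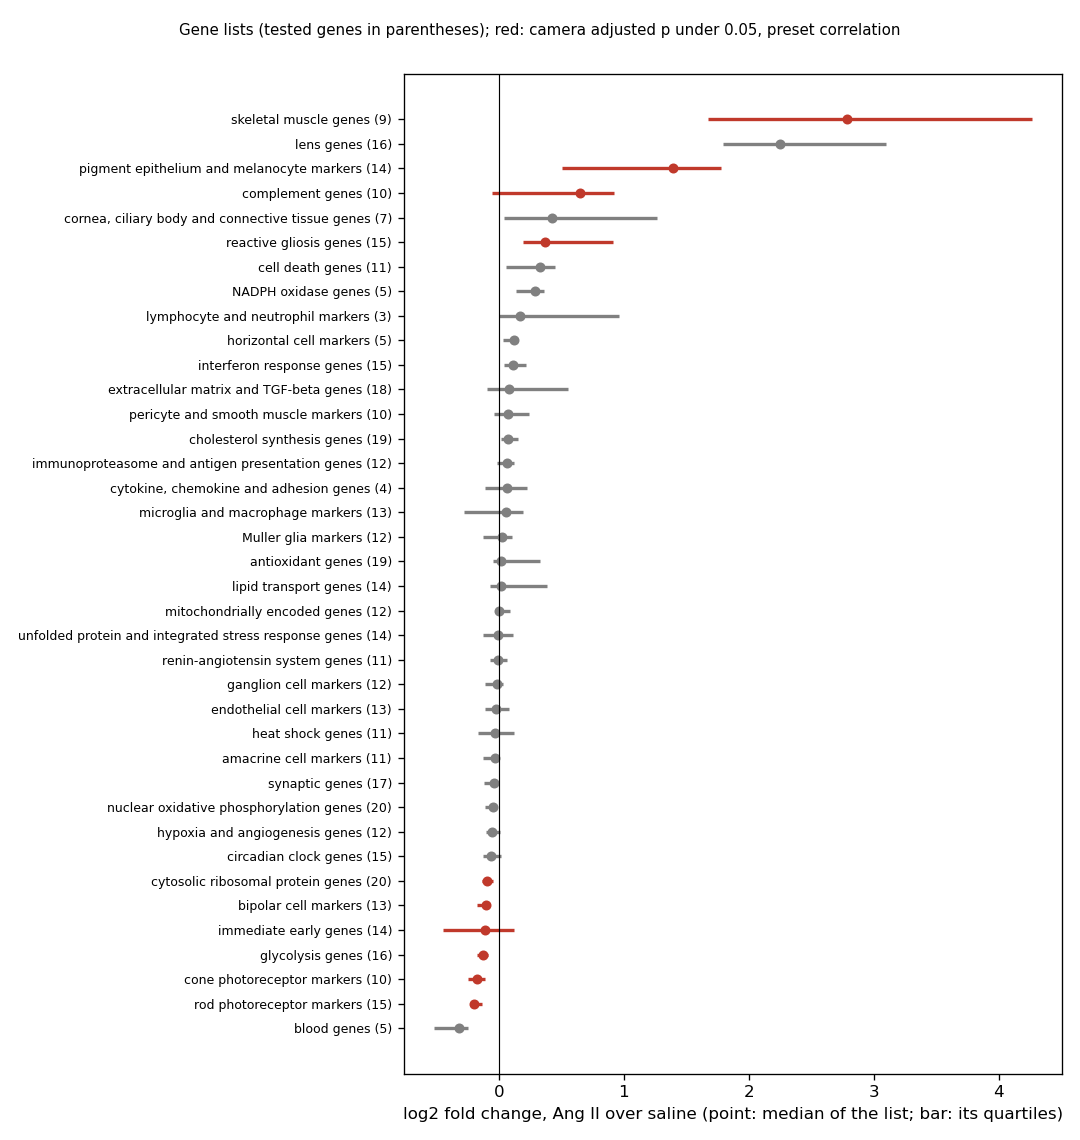
Median log2 fold change, Ang II over saline (points), with quartiles (bars) of the 38 tested gene lists; red marks the 10 lists with a camera adjusted p under 0.05 at the preset correlation. Pigment epithelium markers lie at 1.40 and rod markers at -0.20, and 0 lists were called with an estimated correlation.

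Across the lists, camera called 10 of 38 with the preset correlation, 4 higher and 6 lower. With an estimated correlation 0 were called, 3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.437. Tissues next to the retina contributed unevenly to the libraries. Skeletal muscle genes had a median of 2.79 and a camera adjusted p of 0.0235 (adjusted p = 0.688 with an estimated correlation), and Ang II replicate 3 held 0.0422% of its counts in them (Wilson 95% interval 0.0412 to 0.0432) against at most 0.00242% elsewhere. Myh4, Myh1, Atp2a1 and Tnnt3 had log2 fold changes of 6.77 ± 3.35, 4.32 ± 2.21, 4.27 ± 2.47 and 4.09 ± 2.49, and 0 members passed when adjusted over the list alone. Without that library the adjusted p was 0.888 with the direction turned, limma-voom with quality weights also turned it (0.598), and the call also ended without saline replicate 2 (0.116), without saline replicate 3 (0.308), with library size as the scaling (0.0843), with the pigment epithelium covariate (0.153) and with the replicate block (0.0926). With Ang II replicates 2 and 3 both left out the list was called in the same direction (0.00511). Lens genes took 0.407% of the counts of Ang II replicate 2 and 0.000418% of those of Ang II replicate 4, with an exact permutation p of 0.8 between the groups and a camera adjusted p of 0.178 (median 2.25, Mip at 5.18 ± 2.64, Lim2 at 3.86 ± 2.002). Cornea, ciliary body and connective tissue genes had a median of 0.42 (0.402), with Krt5 at 1.67 ± 0.92 and Krt12 at 1.25 ± 1.21. Blood genes had a median of -0.32 (0.0907, exact permutation p of their share 0.914), with Alas2 at -0.52 ± 0.56 and Hba-a2 at -0.61 ± 0.85. Their share was 0.0153% in Ang II replicate 4 and 0.000917% to 0.00414% in the other Ang II libraries. Alas2 was at -1.28 without Ang II replicate 4 and -0.04 without saline replicate 2, and Hba-a2 at -1.70 without Ang II replicate 4 and -0.25 without Ang II replicate 3. Shares of mitochondrially encoded genes were 2.99% ± 0.206 (SD, n = 4) and 2.96% ± 0.1004 (SD, n = 3), with an exact permutation p of 0.8286, and the share of muscle genes gave an exact p of 0.714. The 5 shares had adjusted p from 0.143 to 0.914.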

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

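The tests of the gliosis pattern below were chosen after the result was seen. Each gene or share here had 1 Ang II library far from the other 3, by a rule that chance meets in about 1 of 20 groups of 4; of 114 items examined, 14 met it, and 11 of the 14 concern Ang II replicate 3.

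In Ang II replicate 3, Gfap was at 79.8 CPM (6.84 to 8.05 CPM in the other Ang II libraries), Edn2 at 30.5 CPM (1.09 to 3.18), Serpina3n at 53.4 CPM (3.14 to 8.80), Osmr at 29.7 CPM (16.0 to 17.3) and Cfi at 2.59 CPM (1.25 to 1.34). Carry-over of myelinated nerve is weakly argued against, because the mean log2 level of the measured nerve and myelin genes, such as Mbp, Mag, Cnp and Prx, was 0.00668 above the highest of the other 6 libraries. That highest value was in Ang II replicate 2, where Prx was at 4.34 CPM, and saline replicate 2 followed (2.68, 2.67 and 2.31 in this order). Nerve without myelin was not tested. In Ang II replicate 3 Mbp was at its lowest of all libraries (43.6 CPM) and Cnp at its highest (25.6 CPM). Of the 11 tested gliosis genes other than Gfap, Edn2, Serpina3n and Osmr, 8 had their highest level in this library, where 1.57 would be expected by chance, which is consistent with gliosis in the tissue of that library as a hypothesis. The 11 genes move together, so this count carries no p-value. RNA from other tissue stays open, since the same library also held most muscle RNA, and an injury or an effect of Ang II in the source of that library stays untested with 1 library.

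The same library was set apart by skeletal muscle genes, with Myh4 at 85.0 CPM (at most 1.57 in the other Ang II libraries), Myh1 at 23.8 CPM (at most 1.93), Atp2a1 at 154.7 CPM (at most 4.59), Tnnt3 at 31.4 CPM (at most 1.53) and a share of 0.0422% of its counts in muscle genes (at most 0.00196%). Its Gngt1 level of 501.3 CPM was above the 462.0 to 466.0 CPM of the other Ang II libraries. In Ang II replicate 2, the lens gene Mip was at 66.9 CPM (0 to 10.7 in the others) and the cone gene Pde6c at 103.5 CPM (78.8 to 80.2). Atp5b was low in Ang II replicate 1, at 884.8 CPM against 917.8 to 921.0 CPM.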

How the results depend on the processing

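The pigment epithelium covariate, the joint omission of Ang II replicates 2 and 3 and the newer edgeR dispersion were chosen after seeing the data. The count of 0 genes called stayed 0 under every other scaling, a filter of CPM of at least 1, no robust dispersion, protein-coding genes alone, removal of tissue genes, the fold threshold, an adjusted p under 0.1, the pigment epithelium covariate and legacy = FALSE. It became 98 (87 higher, 11 lower) with no filter, 35 (31, 4) with DESeq2, 114 (98, 16) with limma-voom and quality weights, 2 (2 higher) with the lens covariate, and 1 (1 higher) without Ang II replicates 2 and 3; the cause was not tested. Leaving out each library in turn gave 0 to 117 genes called, 0 to 103 higher and 0 to 14 lower, with the upper values without saline replicate 3 and 0 in the other 6 cases. The replicate block gave 56 genes (52 higher, 4 lower); same-numbered libraries deviated from their group means with correlations of -0.07, -0.02 and 0.05, and no Ang II library correlated best with its own number, so the numbers were not taken to pair the libraries.

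The same 10 lists were called with DESeq2 size factors, upper quartile scaling and the CPM filter. With library size as the scaling 10 were called, 8 of them shared (without muscle and complement genes), and with the lens covariate 10, 9 of them shared (without immediate early genes). The count became 13 with limma-voom and with the replicate block, 12 with no filter and without robust dispersion, 11 with protein-coding genes, 9 without Ang II replicates 2 and 3, 8 with tissue genes removed, 17 at an adjusted p under 0.1, 5 with the pigment epithelium covariate (rod and ribosomal protein genes of the 10, and newly the lens, oxidative phosphorylation and hypoxia lists), 0 with an estimated correlation and 0 with fry, and 5 to 15 when each library was left out, the lowest without saline replicate 1. Pigment epithelium, rod and bipolar lists were called in all 7 of these. The pigment epithelium median ranged from 1.05 to 2.12 there. The median of all genes moved by at most 0.05 between scalings.

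Leaving out a library moved 61 of the 108 named genes by over 1.5 times. Of 2352 log2 fold changes of the 108 named genes under the alternatives, 2250 kept their direction and side of the threshold, 68 newly passed, and 34 in 21 genes turned sign, none of them past the threshold. With the pigment epithelium covariate the turned values were Calb1 0.022, Clu -0.0041, Ighm 0.29, Acta2 -0.29, Lim2 -0.13, Alas2 0.53, Nln -0.14, Cat -0.0059, Il18 -0.045, Psme2 -0.029, Hk2 0.43, Ldha 0.0092 and Per2 0.19. Without Ang II replicates 2 and 3 they were Calb1 0.000849, Serpina3n -0.18, Ighm 0.059, Mip -2.10, Lim2 -0.70, Alas2 0.094, Hba-a2 0.084, Agt 0.063, Ace 0.079 and Gfap -0.22, and the gliosis list turned (adjusted p 0.714). With limma-voom they were Atp2a1 -0.30, Tnnt3 -0.74 and Agt 0.25, and the muscle list turned (0.598). Agt was 0.034 with library size as the scaling. With each library left out in turn, Gfap ranged from -0.29 to 1.76 and the adjusted p of the muscle list from 8.34e-05 to 0.888, both turning without Ang II replicate 3, while Agt ranged from -0.18 to 0.12 and Ace from -0.21 to 0.056. Depth limits the angiotensin receptor genes, which had 0 to 27 counts per library.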

Other observations

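Tests of a transcriptional change in the pigment epithelium, of dilution of rod RNA (with its models on the pigment epithelium score and share), of the ratios to Rpe65 and of other splits for genes called by edgeR were set up after the result was seen; the other tests below were set up before. The 117 genes that edgeR called without saline replicate 3, chosen after their values were seen, were largely higher in Ang II (103), and 7 of them belong to the pigment epithelium list. They included Lrat (log2 fold change 3.32, adjusted p = 3.30e-08), the retinol ester synthase gene of that tissue, Slc16a8 (2.77), its lactate transporter gene, Kcnj13 (3.18), its potassium channel gene, Ttr (3.01) and Mfrp (2.89). DESeq2 on all 7 libraries called 35 genes, of which 28 are among these 117, including Tyr, Kcnj13, Slc4a5 and Wls on the higher side, with Ier2 and Ckmt1 among its 4 lower genes.

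All 7 libraries carried Y-linked transcripts, with Ddx3y from 52.7 to 80.5 CPM, and 0 to 13 counts of Xist. Of 4 tested sex-linked genes, Eif2s3y (0.39 ± 0.13) and Ddx3y (0.31 ± 0.11) passed when adjusted over the list alone (0.0279 for both) and not over all genes. Gapdh had 15.5 to 111.4 CPM, far below the other glycolysis genes. A gene with many near copies can have such values when shared reads are dropped, which the values here do not test. Its counts were 1314 in Ang II replicate 2 and 1823 in saline replicate 3, and 221 to 403 in the other libraries. The reason for this difference between libraries was not tested.

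Other splits of the 7 libraries into 4 and 3 do not exclude chance for the counts of lists and of genes called by DESeq2. For edgeR they cannot say anything, since a count of 0 is reached in 35 of 35 splits by construction (highest other 1). The 10 lists called were reached or passed in 9 of 35 (highest other 16), and the 35 genes called by DESeq2 in 5 of 35 (highest other 91). The split with 91 set Ang II replicates 1 to 3 with saline replicate 2 against the rest, so part of the structure of these libraries runs across the treatment.

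Pigment epithelium genes were higher in Ang II under each scaling, with a median of at least 1.40 under the other 3. The result therefore did not depend on the choice among these scalings. They moved the median of all genes by at most 0.05, so this was a weak test of scaling between libraries. Different carry-over of pigment epithelium RNA into the dissected retina stays possible. The 100 genes outside the list that followed its score most closely within groups had a median log2 fold change of 0.17, against -0.04 to 0.04 for the central 95% of 10000 random lists matched on expression. Those 100 genes were chosen to move together (within-group correlation of at least 0.93), and the random lists were not. That interval is therefore too narrow to judge an excess, and the comparison decides nothing. Across libraries Rpe65 ranged 10.3-fold while its ratios to Rgr, Ttr, Rdh5 and Lrat ranged 1.28, 1.45, 1.35 and 2.32-fold, but list members such as Mitf (0.51), Tyrp1 (0.51), Pmel (0.26) and Mlana (-0.14) had far smaller log2 fold changes than Rpe65. A change of transcription in pigment epithelium cells under Ang II cannot be told apart from it: the share of counts gave the smallest exact permutation p possible (0.0286), and the amount of that tissue in each sample was not measured.

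Rod genes were lower under each scaling, at most -0.16 as a list median under the other 3. Their direction therefore did not depend on the choice among these scalings. As the scalings differed so little, this was a weak test of scaling as the cause. With the pigment epithelium score as a covariate the rod list kept its call at the preset correlation (camera adjusted p 1.31e-05, median -0.25) while the cone and bipolar calls ended, which counts against dilution by pigment epithelium RNA. Without the covariate, however, the rod call itself was lost with an estimated correlation (adjusted p = 0.437) and with fry (adjusted p = 0.327). The rod difference over libraries was -0.17 ± 0.05 (SE) without a covariate. It was -0.21 ± 0.09 (4 residual degrees of freedom) with that score and -0.16 ± 0.11 with the pigment epithelium share of counts. The difference stayed about as large, where dilution would make it smaller, but its standard errors with a covariate were wide. These models therefore cannot tell dilution apart from a change in rods. The slope of the rod score on the pigment epithelium score was 0.03 ± 0.05 within groups, where dilution would give a negative one, but the slope on the share was -0.06 ± 0.87. The rod score difference of -0.17 had an exact permutation p of 0.0286, the smallest possible and not adjusted over lists. The amacrine and ganglion score differed by -0.06 (exact permutation p = 0.514). The rod score minus the amacrine and ganglion score differed by -0.11 between the groups (exact permutation p = 0.543), with Ang II replicate 4 lowest. That contrast therefore cannot tell a change in rods from a shift shared with those cells.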
